A study of Mus musculus with 6 samples.

How the data were processed

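The labels describe 6 small RNA sequencing libraries from vesicles of RAW264.7 cells, 3 control and 3 treated with RANKL at 50 ng/ml. Per the labels' protocols, osteoclasts were induced for 5 days and then kept in medium with vesicle-depleted serum for 48 h, and vesicles were collected by ultracentrifugation at 110000 g for 70 min. No matching culture or conditioning time was read from the labels for the control libraries, so the groups may differ in more than RANKL. The series' design text describes other centrifugation steps and medium with 10% fetal bovine serum, so the serum the vesicles were collected in is not settled by the labels. Libraries were made with a TruSeq small RNA kit and read for 50 bases, per the labels' protocols.

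Per the labels' protocols, the authors processed the reads with ACGT101-mir. Adapters and low-quality sequences were removed, lengths of 18 to 26 nt were kept, sequences other than miRNAs were filtered against mRNA, RFam and Repbase, and miRNAs were identified against precursors and the genome. Its version, the miRBase release, the mapping rules and the genome build are not given in the sources used here. A filter that misses a fragment of another RNA, or a search over the precursors of several species, can change which species a table lists and how they are named.

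One table of 8 species, with no header line, was analysed. Its row numbers are not consecutive, so it may hold a part of a longer list, and counts over the 8 describe this list alone. Each row pairs a species with its sequence and length, a hairpin with its position, sequence, structure and folding energy, and the miRBase precursors it was named for. Per the values in the deposited table, the percent value given for each hairpin is its GC content, which was the same to 1 decimal when recomputed for all 8. The unit of the deposited folding energy is not stated. The hairpins of 4 of the 5 mouse miRNAs had exactly the start and end of their gene in GENCODE M21, so positions were read as 1-based GRCm38. The table also has 12 columns of per-library values without names. A column was to be assigned to a library only by its name, so these 12 columns were not used, whatever their order or values. Depth per library, replicate spread and precision are therefore not given.

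The design fixed before the data were examined was a test of RANKL-induced against control libraries, of fixed lists of miRNAs and of classes of names, with its alternatives. None of it could be run without an assignment of the columns, and the rule for named miRNAs, which rested on fold changes and levels, was replaced by naming all 8 species. That rule took miR-5134-5p, the miRNAs with the largest changes past the threshold and the most abundant ones. All analyses below were chosen after the table was seen.

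Each species was placed in its listed hairpin without gaps at the position with the fewest mismatches, and compared with the registered miRNA given in the same row. Overlaps with genes and exons were taken from GENCODE M21, and the bounds of Snord93 and the tRNA genes also from RefSeq's GRCm38.p6 annotation. Exact matches were searched on both strands of the 141767 GENCODE transcripts. Hairpins were folded with RNAfold 2.7.2 at its default settings, and each minimum energy was compared with 1999 shuffles of the same hairpin that keep its dinucleotide counts. The one-sided permutation p is the share of shuffles at or below the observed energy, the observed one included, adjusted over the 8 hairpins by the Benjamini-Hochberg method. This test was tested on simulated data with 199 shuffles each, at an unadjusted p of 0.05. It called 100 of 100 planted hairpins, which had perfect stems, and 5 of 100 shuffled sequences. The first rate says little about power for the listed hairpins, whose stems are imperfect and most of which are longer. The second checks only the error rate, since shuffled sequences were set against further shuffles of themselves. Seed sites were searched in the longest annotated 3' UTR of each of 21020 genes, as matches to nt 2 to 8, or to nt 2 to 7 followed by A. Python 3.11.15 and matplotlib 3.10.9 were used.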

Results

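The study addressed which small RNAs are carried by extracellular vesicles (exosomes) released by osteoclasts, the cells that resorb bone. RAW264.7, a mouse macrophage-like cell line, was cultured without RANKL, or with 50 ng/ml RANKL, the cytokine that drives osteoclast formation. The labels describe 6 small RNA libraries, 3 control and 3 RANKL-induced, each from a separately numbered sample. They do not say whether the numbers stand for separate cultures. The table analysed here holds 8 small RNA species and has no column names, and how the 8 were chosen is not given in the sources used here. Its 12 columns of per-library values could therefore not be assigned to a library or group by name, and they were not used. No abundance, depth or fold change is given below, and the control against RANKL-induced comparison was not made. What could be measured is what each listed species is, where it lies in the mouse genome (GRCm38), how it differs from the miRNA registered in miRBase, and how stably its hairpin folds.

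Of the 8 species, 5 were named as mouse miRNAs, all from the 5p arm of their hairpin. One was a candidate with no miRBase name, and 2 carried the names of cattle and Chinese hamster miRNAs. Only 1 of the 5 mouse species, miR-3079-5p, had both ends of the registered miRNA. The other 4 differed from theirs by 1 or 2 nt at 1 or both ends. All 5 matched their mouse hairpin without a mismatch, bases beyond the registered ends included. The seed, taken as nt 2 to 8, was that of the registered miRNA in 4 of the 5, the exception being miR-5134-5p. The authors' deposited table gave all 8 species the same word for their level, middle, with no bounds for it.

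miR-5134-5p, the miRNA named in the study's title, was listed as a 21 nt species, TGGCAGAAAGGGCAGCTGTGA, at chromosome 17, 24234574 to 24234594, on the minus strand. The registered miR-5134-5p, TTGGCAGAAAGGGCAGCTGTG, is also 21 nt long. The listed species began 1 nt later and ended 1 nt later, which changed its seed from TGGCAGA to GGCAGAA. Its 78 nt hairpin, at 24234527 to 24234604, had the bounds of the annotated gene Mir5134. It lay on the sense strand of Ccnf, which encodes cyclin F, the F-box subunit of a ubiquitin ligase. The 5p species lay in intron 9 of Ccnf (24234535 to 24237080, 2546 bp), and the last 8 nt of the hairpin lay in exon 10 (24234370 to 24234534). The registered 3p arm ended in AG at 24234535, the last base of the intron, so 0 nt separated it from exon 10. The registered 5p arm began 2485 nt from the start of the intron. Within 10000 bp of the hairpin lay 1 other annotated miRNA gene, Mir6965. In the deposited structure 19 of the 21 nt of the listed species were paired. The hairpin's minimum folding energy from RNAfold was -30.1 kcal/mol, against a median of -21.3 kcal/mol in shuffles that kept its dinucleotide counts (one-sided permutation test, Benjamini-Hochberg adjusted p = 0.0200 over the 8 hairpins).

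**Figure D1:**
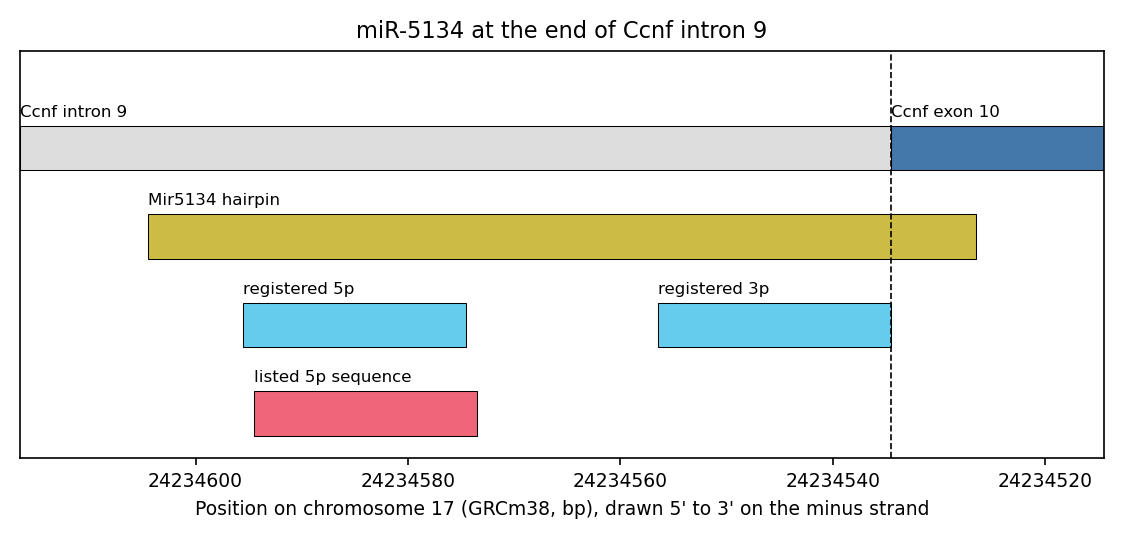
Map of the miR-5134 hairpin on chromosome 17 (x axis, GRCm38 position in bp, reversed so that the minus strand reads 5' to 3'; the bars have no y scale). The registered 3p arm ends at the dashed line between intron 9 and exon 10 of Ccnf, and the listed 5p species starts and ends 1 nt after the registered 5p.

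The other mouse miRNAs lay inside or outside host genes. miR-330-5p was listed as TCTCTGGGCCTGTGTCTTAG, 20 nt, which lacked the last 2 nt of the 22 nt registered form. It lay at chromosome 7, 19181486 to 19181505, plus strand, on the sense strand of Eml2, which encodes a microtubule-associated protein. All 20 nt fell in exon 1 of an Eml2 transcript (19181332 to 19181548) as well as in Mir330. Its sequence occurred in those 2 transcripts of the 141767 searched, so a read could come from either. The listed hairpin extended 11 nt before and 5 nt beyond the annotated Mir330 gene. The table named 14 miRBase precursors for it, from mouse and other species. miR-7669-5p was listed as AGTACCACCATACACAGCTTTTGT, 24 nt, 1 nt longer at its 3' end than registered. It lay at chromosome 3, 90011187 to 90011210, minus strand, in an intron of Ubap2l on the sense strand and opposite the lincRNA Gm19710. miR-3079-5p, TTTGATCTGATGAGCTAAGCTGG, lay at chromosome 15, 76290932 to 76290954, minus strand, in an intron of Spatc1 but on the opposite strand. miR-743b-5p, TGTTCAGACTGGTGTCCATCAT, was 22 nt long and 1 nt longer at its 3' end than registered. It lay at chromosome X, 66777301 to 66777322, minus strand, in no other annotated gene, with Mir742, Mir743 and Mir883a within 10000 bp. For miR-7669, miR-3079 and miR-743b, as for miR-5134, the hairpin had the start and end of the annotated miRNA gene.

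The candidate, PC-3p-12307_23, had the sequence AAAGGATTTACCTGAGGCCAA and lay at chromosome 5, 23852261 to 23852281, plus strand. Of its 21 nt, 20 were identical to nt 52 to 71, the 3' end, of the 71 nt annotated small nucleolar RNA Snord93 (23852210 to 23852280), on the same strand. Snord93 belongs to the C/D box class of RNAs that guide 2'-O-methylation. The tetramer CTGA, the sequence of box D, stood at nt 63 to 66 of Snord93 and began at nt 12 of the candidate. Within the shorter RefSeq bounds of the gene, 17 of the 21 nt were inside Snord93. Snord93 and the candidate's 123 nt hairpin lay in an intron of the lincRNA 2700038G22Rik. The labels' protocol describes a filter against RFam, a collection of structured RNA families, for sequences other than miRNAs.

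**Figure D2:**
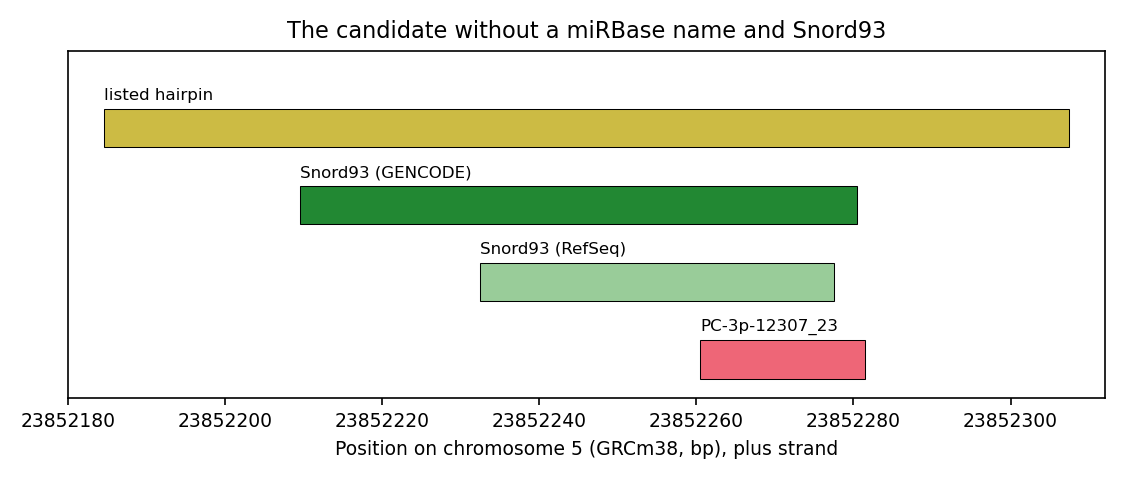
Map of the candidate PC-3p-12307_23 on chromosome 5 (x axis, GRCm38 position in bp, plus strand; the bars have no y scale). Its 21 nt overlap the 3' end of Snord93 by 20 nt in the GENCODE bounds and by 17 nt in the RefSeq bounds.

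The species named for cattle and hamster each had 1 mismatch to the mouse locus the table gives for them. The species named bta-miR-2284ab, 21 nt long, was identical to the registered cattle miRNA and differed from the mouse locus by T20C. Here and for the next substitution the species' base comes first, then its position from the 5' end, then the base of the locus. The locus, chromosome 10, 121769967 to 121769987, plus strand, lay in no annotated gene, and the nearest, Srgap1, was 11004 bp away. The species named cgr-miR-1260, 19 nt long with 1 nt added at its 3' end, differed from the mouse locus by G9T. That locus, chromosome 11, 34430556 to 34430574, plus strand, lay opposite an intron of Dock2, a Rac activator of blood cells. Neither sequence occurred in any of the 141767 annotated mouse transcripts on either strand. Those transcripts cover neither locus, so the search does not tell whether the species are of mouse origin. The candidate at Snord93, which matched its listed mouse hairpin without a mismatch, had no exact match there either. Both sequences are left out here.

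The listed hairpins of 4 of the 5 mouse miRNAs folded more stably than shuffled sequence. Registered miRNAs come with a hairpin precursor, so a stable fold is no independent evidence for them. Against dinucleotide shuffles the hairpins of miR-5134, miR-743b, miR-3079 and miR-7669 passed an adjusted permutation p of 0.05, and the other 4 did not. The miR-3079 hairpin folded to -55.6 kcal/mol against a shuffled median of -24.2 kcal/mol, with an unadjusted permutation p of 0.0005, the smallest that the shuffles can give (adjusted p = 0.0040). The miR-743b hairpin folded to -28.8 against -15.9 kcal/mol (permutation p = 0.0010, adjusted p = 0.0040), and the miR-7669 hairpin to -25.7 against -15.1 kcal/mol (permutation p = 0.0035, adjusted p = 0.0093). The listed miR-330 hairpin reached -42.5 against -36.7 kcal/mol (permutation p = 0.0725, adjusted p = 0.0967). When the 98 nt registered precursor was folded in place of the 114 nt listed hairpin, its unadjusted permutation p was 0.0085, and miR-330 passed after adjustment over the 5 mouse miRNAs. For the candidate at Snord93 the values were -34.5 and -27.8 kcal/mol (permutation p = 0.0490, adjusted p = 0.0784). The locus of the species named for cattle gave -31.2 against -26.6 kcal/mol (permutation p = 0.1065, adjusted p = 0.1217), while the authors' deposited table lists -35.3, with no unit, for the same hairpin. The 30 nt locus of the species named for hamster formed no stable fold, with 0.0 kcal/mol for it and for the shuffled median. Its adjusted permutation p = 1.0000 was fixed by that energy, since no shuffle can fold above 0.0 kcal/mol. When single bases were shuffled instead, the count that passed rose from 4 to 7 of the 8. In the deposited structures the paired share of the species was 19 of 21 nt for miR-5134-5p and 17 of 20 for miR-330-5p. For miR-743b-5p it was 18 of 22 nt, for miR-3079-5p 18 of 23 and for miR-7669-5p 19 of 24. It was lower for the candidate (15 of 21), bta-miR-2284ab (10 of 21) and cgr-miR-1260 (3 of 19).

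**Figure D3:**
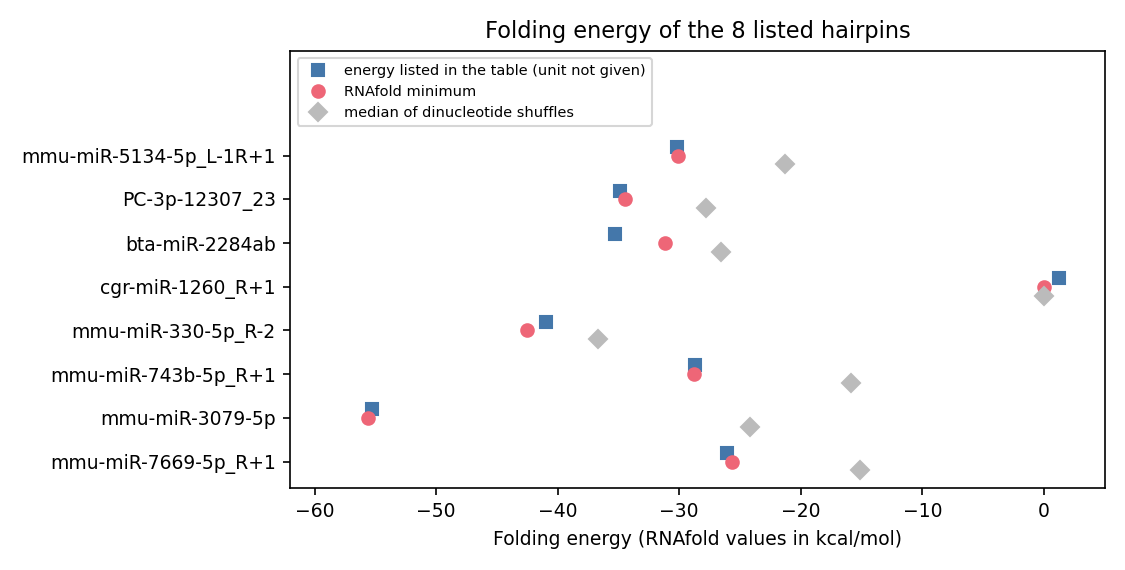
Folding energy (x axis; RNAfold values in kcal/mol, listed values with no unit given) of the 8 listed hairpins (y axis). Circles mark the RNAfold minimum, squares the energy listed in the table and diamonds the median of the dinucleotide shuffles; the gap is widest for miR-3079, at -55.6 against -24.2 kcal/mol, and absent for cgr-miR-1260.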

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

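All alternatives here were chosen after seeing the data. The alternatives fixed before the data were examined (other pseudocounts, filters, scalings, tools and set tests, length variants summed, a replicate block, libraries left out) were not run, because the per-library columns have no names. No paired analysis was possible because the columns carry no replicate numbers or group names. The count of hairpins more stable than shuffled sequence was 4 of 8 with dinucleotide shuffles and 7 of 8 with single-base shuffles, which gained the candidate at Snord93 (adjusted permutation p = 0.0413), the bta-miR-2284ab locus (0.0474) and miR-330 (0.0328). With registered precursors it was 5 of the 5 mouse miRNAs, adjusted over these 5 alone. For miR-330, without the 16 nt of flank in the listed hairpin, the unadjusted permutation p was 0.0085 against 0.0725, so its p moved with the flank as well as with the shuffle; the calls for miR-5134, miR-743b, miR-3079 and miR-7669 were kept in both alternatives. The overlap of the candidate with Snord93 was 20 nt in GENCODE and 17 nt in RefSeq bounds. Matches to the 6 nt seed (nt 2 to 7) of the shifted miR-5134-5p numbered 2 in the Stat3 3' UTR. Sites of 7 nt or more numbered 0 there. The share of other genes with such 6 nt matches was not counted, so the 2 cannot be called many or few. The other site counts in Jak2 and Stat3 did not change with the 6 nt seed. No annotated 3' UTR of either gene held more sites than the longest. That count was the most in any annotated 3' UTR, the longest included, so it could not fall. Whether the other annotated Jak2 3' UTRs hold the site was not counted.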

Other observations

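Of the tests in this part, those on seed sites and on the stability of the Snord93 hairpin were set before their results were seen; the others were chosen after. No biological explanation based on the study's groups was tested, since no value was assigned to a group.

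The listed miR-5134-5p species starts 1 nt later than the registered miRNA, which shifts its seed. Whether the registered form was also present in these vesicles is not known, since the list may be part of a longer one. The study's title names the JAK2/STAT3 axis as the target, and seed sites were therefore counted in the mouse 3' UTRs. A Jak2 3' UTR site for the registered seed was found: the 1232 nt Jak2 3' UTR held 1 site, a 7 nt match (nt 2 to 7 followed by A) at nt 818 to 824. Of 3099 genes with a 3' UTR of similar length, 20.2% held at least 1 such site, so a single site is common. For the seed of the listed species, the Jak2 3' UTR held 0 sites, while 22.8% of the same genes held at least 1. The 6 bases of the registered seed matched at the Jak2 site also stand in the listed species, 1 nt nearer its 5' end. The Jak2 counts therefore separate the forms only by where the match starts. The 3701 nt Stat3 3' UTR held 0 sites for the registered seed and 0 for the shifted seed, and in genes with 3' UTRs of similar length the shares with a site were 45.1% and 51.5%. With matches to the 6 nt seed counted instead, Stat3 held 2 for the shifted seed and 0 for the registered one. The 6 bases of that shifted seed also stand in the registered form, 1 nt further from its 5' end. These 2 matches therefore do not separate the forms, and the share of other genes with such matches was not counted. Whether either form acts on Jak2 or Stat3 was not tested. Sites outside 3' UTRs, 6 nt matches that start elsewhere than at nt 2, and pairing with less than a 6 nt seed match were not searched.

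The registered 3p arm of miR-5134 ends at a splice site of Ccnf, as the 3' arms of mirtrons, hairpins cut out by splicing, do. The annotated hairpin itself runs 8 nt further, into exon 10. A mirtron with both ends made by splicing is argued against by the 2485 nt between the start of the intron and the 5p arm. A 5'-tailed mirtron, with only the 3' end made by splicing, stays open as a hypothesis. The position of the 3p arm, 0 nt from the end of the intron, is the observation that raised it and is no test of it, and whether the microprocessor cuts this hairpin was not tested.

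The candidate PC-3p-12307_23 may be a fragment of Snord93 rather than a miRNA: 20 of its 21 nt are the 3' end of that snoRNA, box D included. That overlap raised the explanation and is no separate test of it. The candidate's last nt, at 23852281, lies past the end of Snord93 in GENCODE (23852280) and in RefSeq (23852277). It is therefore not wholly a fragment of the snoRNA as annotated. A hairpin precursor is not excluded. The folding energy of the candidate's hairpin lay below the shuffled median but did not pass (adjusted permutation p = 0.0784). With single-base shuffles it passed (adjusted permutation p = 0.0413). Those shuffles do not keep dinucleotide counts, however, and 7 of the 8 hairpins passed against them. The hairpin contains the whole snoRNA, so either processing route stays open. The labels describe an RFam filter for sequences other than miRNAs; whether this species was put through it is not given in the sources used here.

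The species named for cattle could be RNA of bovine origin, such as serum RNA, or a mouse RNA given the nearest registered name. It equals the cattle miRNA and has 1 mismatch to the mouse locus, but a 1-base difference can also be a sequencing error, and neither the mouse nor the cattle genome was searched. The 2 origins cannot be told apart here. The species named for hamster has the same number of mismatches and a registered sequence ending in CCA, the triplet added to the 3' end of mature tRNAs. The listed species runs 1 nt past that CCA, which goes against the unmodified 3' end of a tRNA. Its only mismatch to the mouse locus is G9T, so the CCA and the base after it match that locus. A tRNA end with an added base stays open. Of the 430 tRNA genes in RefSeq's table, 0 overlap the mouse locus, which decides little, since the added CCA is not part of the gene and the species has a mismatch to that locus. The sequences of nuclear tRNAs were not searched. The 30 nt mouse locus had no stable fold (listed energy 1.2).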
